A study of Mus musculus with 21 samples.

How the data were processed

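Total RNA from mouse liver was extracted with Trizol, carried a biotin label and was prepared with a 3-prime IVT labelling protocol, per the labels' protocols. Signals were processed with GCRMA, which corrects background and summarises the probes of each probe set, per the submitters' processing notes; the version was not given. The deposited values are on a log2 scale, as read from their range, which runs from just over 1 to under 16 with 2 decimals. Other steps the authors took are not given in the sources used here. The table held 22690 probe sets on 21 arrays, and no scanner files were used, so normalization was kept as deposited. Array medians lay between 3.79 and 4.08. An array gives no count of molecules, so the number of arrays per group sets the precision.

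Groups were taken from the labels: genotype and day after surgery, with the mouse number as the replicate. Group sizes were 6 for KO on day 0 and 3 for each of the other 5 groups. The comparisons, tests, alternatives, gene lists and rule for named genes were fixed before the data were examined.

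Probe sets were named through the platform annotation supplied with the values. Of all probe sets, 64 were array controls, 20380 had 1 gene symbol, 691 had several and 1555 had none here; only those with 1 symbol were used. By Entrez ID, 20351 were matched to a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used for names and for which genes lie near each other. Of several probe sets of a gene, the one with the highest mean over all arrays stood for it, which left 12393 genes, 4956 of them with several probe sets. Genes with a log2 value above 4 in at least 3 arrays were tested, 7320 in all. Ccnb1, Trp53, Spp1, Afp and Tnf were to be named but did not pass this filter and were not tested.

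Each comparison was a contrast in 1 limma model of all 6 groups (lmFit and eBayes, limma 3.58.1 in R 4.3.3), with 15 residual degrees of freedom. Adjusted p-values are two-sided, by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. Changes are differences of log2 values with their standard error (SE). Of 34 lists of genes for liver pathways and cell types, those with at least 5 tested genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation; 503 of 759 list genes were tested. Of 114 list results that passed with the preset correlation, 8 passed with the estimated one. Members were also adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

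Genes were named by rule. Part (a) was Abcb4 in every sample. Part (b) took, among genes past the threshold whose groups did not overlap, the 8 largest rises and 8 largest falls of each comparison of 2 groups, and the 5 largest in each direction of an interaction. Part (c) took up to 4 members of each list with the largest change among those past the test over all genes, or the member with the smallest p where none passed, given as values. Part (d) was Cdkn1a, Ccnb1, Cdk1, Mki67, Ccnd1, Trp53, Col1a1, Krt19, Spp1, Afp, Tnf, Cyp7a1, Plin2, Alb, S100a8 and Saa1. The text names any subset of (b) with 1 annotated gene that is not a predicted gene, and genes outside the rule are said to be named after their values were seen.

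The labels give the day 0 and later samples of a mouse the same number, so the numbers pair samples of 1 animal. In 9 such pairs the correlation of deviations from the group means ran from −0.0568 to 0.303, with a median of 0.119, against −0.0107 for samples of different mice and groups; 5 pairs were above 0.1. Of 9 later samples, 3 correlated best with the day 0 sample of their own mouse. Each had 6 (KO) or 3 (control) day 0 samples to match, so some matches arise by chance. The count alone does not establish the pairing. The mouse was an alternative, as a random block (duplicateCorrelation, correlation 0.108) and as a fixed block within a genotype. For lists under the random block cameraPR was used in place of camera.

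The models were tested on simulated data with 200 of 7320 genes changed by a log2 difference of 1 or 2, and no changed gene was called in the wrong direction. For KO against control on day 0 they recovered 46.5% and 95% of these genes. For day 2 against day 0 in KO they recovered 53% and 92%, and for the day 2 response, KO minus control, 12.5% and 76%. The simulated noise was normal, independent between genes and of equal spread on all arrays, and 200 genes always changed. These shares need not hold for the deposited values, so a count of 0 there does not exclude changes of this size.

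Alternatives were no filter, a filter at log2 6, the mean of a gene's probe sets, every probe set on its own, quantile normalization, centring each array on its median, eBayes with trend and robust, array weights, a fit of only the groups compared, the blocks and leaving out each array. Leaving out the 3 arrays with a Gapdh 3' to 5' difference above 1, the beta-actin difference as a covariate, and only the day 0 arrays of the same mice were added after seeing the data. A larger pseudocount was not run because the values are already log2, and Abcb4 has only 1 named probe set, so its alternative gave no other value.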

Results

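Liver RNA was measured on 21 Affymetrix mouse arrays, each hybridised with total RNA from a single liver sample of a 9-month-old male mouse. Mdr2 knockout mice (KO) lack the transporter, encoded by Abcb4, that moves phospholipid into bile, and the series title concerns inflammation-induced DNA breaks and liver cancer. All mice underwent a 30% partial hepatectomy, and the removed lobe served as the day 0 sample. Day 0 comprised 6 KO and 3 control samples, and days 2 and 6 comprised 3 samples per genotype each. Samples are named by mouse number, and the later KO samples came from the mice that had given the day 0 lobes. Among controls, mice 263 and 265 gave samples on days 0 and 2, mouse 303 on days 0 and 6, and mice 264, 392 and 393 on a later day only. Within a group, replicates were therefore separate mice. The strain was given as FVB129P2 for KO and FVB129P2/FVBNJ for controls, so genotype and strain background were not separate in these comparisons. Array medians lay between 3.79 and 4.08 on the log2 scale, and the small number of arrays per group limits the precision of every value. After the low-value filter, 7320 genes were tested, of which 649 still lay at or under log2 4 on every array of at least 1 group. Signal there is near background, so a difference from such a group is a lower bound on its size, and these genes are named below.

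The targeted gene was examined first. The probe set for Abcb4 lay between 7.25 and 8.96 (log2) in the 12 KO samples and between 9.23 and 10.33 in the 9 control samples, so every array followed its genotype. Mean Abcb4 values were 9.79 ± 0.348, 9.93 ± 0.606 and 10.15 ± 0.0611 (SD, n = 3) in controls on days 0, 2 and 6. In KO they were 8.21 ± 0.512 (SD, n = 6), 7.93 ± 0.0839 (SD, n = 3) and 7.73 ± 0.421 (SD, n = 3). Abcb4 was lower in KO by limma on all 3 days, at −1.58 ± 0.29 (SE, adjusted p = 0.00126), −1.99 ± 0.33 (adjusted p = 0.00266) and −2.41 ± 0.33 (adjusted p = 0.000447). Where this probe set lies relative to the disrupted part of the gene is not given in the sources used here, so its remaining signal does not measure residual transcript.

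**Figure D1:**
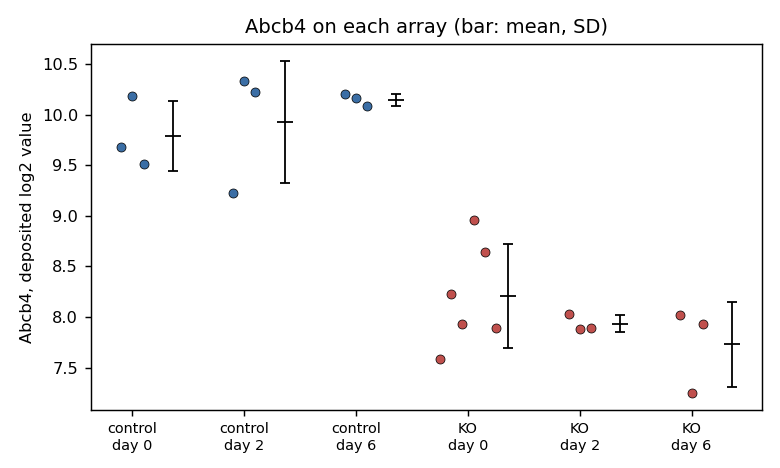
Deposited log2 value of Abcb4 on each array, by genotype and day; points are samples and bars give mean and SD. All 12 KO samples lay at or below 8.96 and all 9 control samples at or above 9.23.

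The arrays carry probe sets at the 3' and 5' ends of control transcripts, whose difference grows as RNA shortens. For Gapdh this log2 difference was 9.5 in control day 2 265, 2.03 in KO day 0 337 and 1.58 in control day 2 263, followed by 0.94 in control day 6 303. The matching beta-actin differences were 5.92, 2.48, 3.91 and 2.72. The mean correlation with the other arrays of the group was 0.947 in control day 2 265, 0.96 in control day 2 263 and 0.962 in control day 2 264, whose Gapdh difference was 0.07. The mean pairwise correlation across genes was 0.956 in control day 2 against 0.9785 to 0.9907 in the other 5 groups. The median SD across genes was 0.475 in control day 2, compared with 0.214 in control day 0 and 0.294 in KO day 0. Comparisons that include these arrays are also given without the 3 arrays whose Gapdh difference exceeded 1, an alternative chosen after seeing the data. It leaves control day 2 with the single sample 264, which is then assumed to vary like the other groups.

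**Figure D2:**
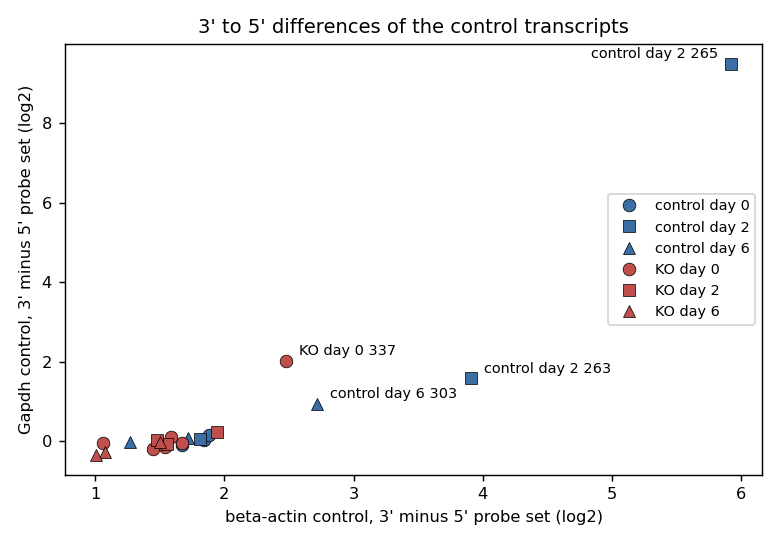
Difference between the 3' and 5' probe sets of Gapdh (vertical, log2) and of beta-actin (horizontal, log2) on each of the 21 arrays, marked by genotype and day. Control day 2 265 stood apart at 9.5 and 5.92, and control day 2 263 and KO day 0 337 lay above 1 for Gapdh.

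**Figure D3:**
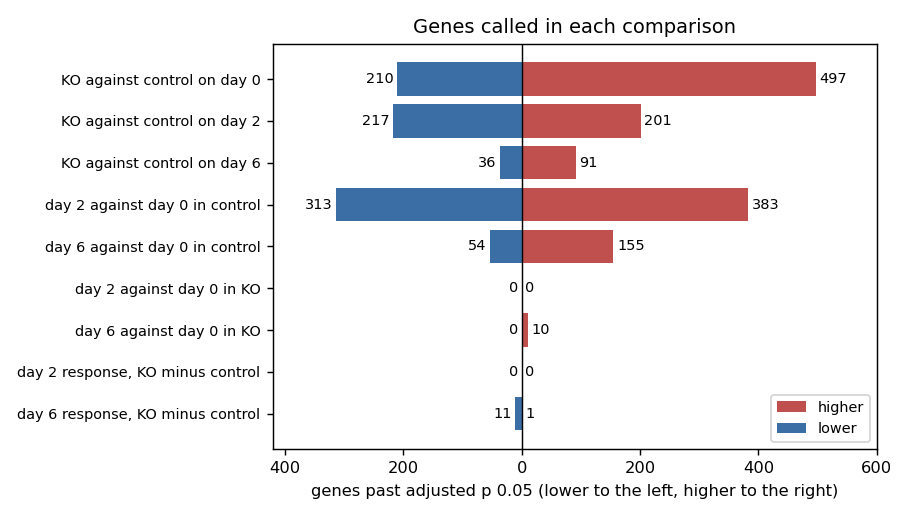
Number of genes past an adjusted p of 0.05 in each of the 9 comparisons, higher to the right and lower to the left. KO against control on day 0 had the highest total, with 497 genes higher and 210 lower, while day 2 against day 0 in KO and the day 2 response, KO minus control, had none.

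KO against control on day 0 compared the livers at surgery, before any response to the resection. Most genes of extracellular matrix and most tumour-associated genes tested were higher in KO. A minority of drug-metabolising and male-biased genes were lower, and neither of those lists passed with an estimated correlation. Of 27 matrix and stellate cell genes tested, 20 were higher in KO, 7 did not pass and none was lower; 22 were higher when adjusted over the list alone. Their median log2 difference was 2.62, with camera adjusted p = 4.39e-18 and adjusted p = 0.125 with an estimated correlation. Their mean, centred per gene, was 1.63 in KO 258 and −0.007 to 0.826 in the other KO arrays. In control it lay between −1.7 and −1.53. Examples were the fibrillar collagens Col1a1 (4.58 ± 0.89, SE) and Col3a1 (4.25 ± 0.56), the proteoglycan Lum (4.31 ± 0.51) and Col6a3 (3.83 ± 0.43). Of 15 oncofetal and liver tumour genes, 9 were higher and 6 did not pass (12 higher when adjusted over the list alone, median 2.75). That list passed with both the preset and the estimated correlation, with adjusted p = 4.45e-12 and 0.0331. Its members included the epithelial surface protein Ly6d (6.47 ± 1.17), the annexins Anxa5 (4.75 ± 0.31) and Anxa2 (4.28 ± 0.42), and the Golgi protein Golm1 (4.42 ± 0.42). Of 11 cholangiocyte and progenitor genes, 5 were higher and 6 did not pass (6 higher when adjusted over the list alone, median 1.38, adjusted p = 1.23e-05, and 0.0344 with an estimated correlation). They included Tspan8 (3.01 ± 0.28), Cd24a (2.75 ± 0.53), Cdh1 (2.62 ± 0.31) and Krt8 (1.90 ± 0.23), whereas the bile duct keratin Krt19 did not pass (0.93 ± 0.36, adjusted p = 0.123). Tspan8 and Cd24a also belong to the oncofetal and liver tumour list, so the results of these lists are not separate.

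Further groups differed on day 0. The pancreas list value, centred per gene, lay between 1.61 and 1.88 in control and between −1.01 and −0.089 in KO. It rests on a single tested gene, too few for camera, so it shows no difference in pancreas markers as a group. Of 13 lipid droplet and uptake genes, 5 were higher (6 higher and 1 lower when adjusted over the list alone, median 1.22, adjusted p = 0.00171, and 0.236 with an estimated correlation). Lipoprotein lipase Lpl was higher by 4.96 ± 0.68 (SE), the fatty acid transporter Cd36 by 3.57 ± 0.53, Apoa4 by 2.74 ± 0.51 and the adipogenic receptor Pparg by 2.58 ± 0.47. The droplet coat gene Plin2 did not pass (0.06 ± 0.35, adjusted p = 0.955). Of 24 cytochrome P450 genes, 8 were lower (1 higher and 9 lower when adjusted over the list alone, median −0.45, adjusted p = 0.000278, and 0.236 with an estimated correlation), including Cyp2c54 (−4.75 ± 1.04) and Cyp2b10 (−2.78 ± 0.63). Of 15 male-biased liver genes, 3 were lower, also when adjusted over the list alone (median −0.75, adjusted p = 0.000387, and 0.236 with an estimated correlation). They were the steroid dehydrogenase Hsd3b5 (−7.05 ± 1.33), Susd4 (−5.21 ± 0.51) and the oxysterol hydroxylase Cyp7b1 (−1.33 ± 0.41, adjusted p = 0.0446, and 0.0504 with the mouse as a random block). Bile acid genes divided: of 23 tested, 3 were higher and 6 lower (3 higher and 10 lower when adjusted over the list alone, median −0.40, adjusted p = 0.00736, and 0.212 with an estimated correlation). The efflux pumps Abcb1b (3.91 ± 0.40) and Abcb1a (2.26 ± 0.38) were higher and the sterol transporter Abcg8 (−2.21 ± 0.41) was lower. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (0.87 ± 1.05, adjusted p = 0.704), nor did albumin, Alb (0.02 ± 0.12, adjusted p = 0.944). The signs of the Plin2 and Alb differences turned with each array centred on its median.

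Proliferation and damage-response genes were also examined on day 0. Of 17 G2/M genes tested, 4 were higher in KO (7 when adjusted over the list alone, median 1.20, adjusted p = 0.000352, and 0.52 with an estimated correlation). The mitotic activator Cdc20 (2.89 ± 0.76, SE), the mitotic kinase Cdk1 (2.29 ± 0.57) and the proliferation marker Mki67 (2.14 ± 0.47) were among them. Of 24 replication genes, 3 were higher and 2 lower, with the helicase subunit Mcm6 higher (2.47 ± 0.50) and thymidine kinase Tk1 lower (−2.08 ± 0.58; 4 higher and 3 lower when adjusted over the list alone, list median 0.48, adjusted p = 0.0382, and 0.52 with an estimated correlation). Of 21 p53 targets, 4 were higher and 1 lower (6 and 1 when adjusted over the list alone, median 0.40, adjusted p = 0.00736, and 0.236 with an estimated correlation). The cell cycle inhibitor Cdkn1a was higher by 3.80 ± 0.86 (adjusted p = 0.00767) and Btg2 by 2.67 ± 0.73, whereas Gadd45a was lower (−1.70 ± 0.52). Of 17 double-strand break genes, 1 was higher, the helicase Blm (0.97 ± 0.29, adjusted p = 0.0429), and 5 were higher when adjusted over the list alone (median 0.33; list adjusted p = 0.0375, and 0.437 with an estimated correlation). Cyclin D1, Ccnd1, was higher by 1.85 ± 0.49 (adjusted p = 0.0224). Among 22 macrophage genes, 5 were higher and the scavenger receptor Cd163 was lower (−3.38 ± 0.29, adjusted p = 7.19e-07). Over that list alone 6 were higher and 1 lower (median 0.79, adjusted p = 0.0131, and 0.52 with an estimated correlation). Outside the lists, the protease inhibitor Slpi (6.23 ± 0.47), the ubiquitin-like Ubd (5.69 ± 0.75) and the caspase Casp12 (5.03 ± 0.36) were among the genes with the largest differences. S100a8 (0.56 ± 0.87, adjusted p = 0.782) and Saa1 (1.91 ± 0.88, adjusted p = 0.209) did not pass.

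In all, KO against control on day 0 called 707 of 7320 genes by limma, 497 higher and 210 lower in KO, and 496 of them differed at least 2-fold. With each array centred on its median, 747 were called, 448 higher and 299 lower. Groups of 1448 genes (19.8%) did not overlap, against 2.38% by chance. Without the 3 arrays with a high Gapdh difference, 885 were called (544 higher, 341 lower), 661 of them shared. The call rested in part on the 3 control arrays, with 357 genes without control day 0 265, 417 without control day 0 303 and 471 without control day 0 263. The calls of Cdkn1a (adjusted p up to 0.0527), Btg2 (0.117), Cdc20 (0.141) and Cdk1 (0.0835) were lost without control day 0 265, and the last 3 also without control day 0 303. That of Cyp2b10 (0.0604) was lost without control day 0 263, and those of Tk1, Gadd45a, Blm (0.302), Ccnd1 and Cyp7b1 without control day 0 265, without 303 and without other arrays. Differences were bounds for Col1a1, Ly6d, Golm1, Tspan8, Cd24a, Krt19, Abcb1a, Cdk1, Mki67, Mcm6, Blm and Ubd, at or under 4 on every control array, and for Susd4 and Cd163, at or under 4 on every KO array.

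KO against control on day 2 compared the regenerating livers in the first days after resection. Matrix and tumour-associated genes were higher in KO, and fatty acid oxidation genes were lower. Of 27 matrix genes, 5 were higher and 22 did not pass (10 higher when adjusted over the list alone, median 1.08, adjusted p = 1.6e-08, and 0.519 with an estimated correlation). Col1a2 was higher by 3.65 ± 0.89 (SE), Col1a1 by 3.56 ± 1.02 (adjusted p = 0.0479), Lum by 2.73 ± 0.59 and Col6a3 by 2.39 ± 0.49. In KO 250, 254 and 258 on day 2, the matrix mean, centred per gene, was 0.021, 1.244 and 1.512. It lay between −0.898 and −0.191 in control. The 2 mesothelium markers tested had a median of −1.53 (none passed over all genes, 1 lower over the list alone). Their mean was 1.168, −1.057 and −1.012 in the same KO samples, so 250 stood apart in both lists. Of 15 oncofetal genes, 7 were higher (9 when adjusted over the list alone, median 1.41, adjusted p = 2e-06, and 0.162 with an estimated correlation), with Anxa5 at 3.63 ± 0.36 and Golm1 at 2.60 ± 0.49. Of 20 fatty acid oxidation genes, 5 were lower and 15 did not pass (11 lower when adjusted over the list alone, median −0.84, adjusted p = 9.85e-05, and 0.519 with an estimated correlation). The omega-hydroxylase Cyp4a14 was at −6.70 ± 1.22, the thioesterase Acot1 at −3.85 ± 1.06, the carnitine carrier Slc25a20 at −1.33 ± 0.22 and Cpt2 at −1.02 ± 0.25. Lpl (4.68 ± 0.78), Casp12 (4.44 ± 0.42) and Cd36 (3.50 ± 0.61) were higher and Cd163 (−4.60 ± 0.34) and asparagine synthetase Asns (−4.28 ± 0.70) lower.

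On the same day, 3 of 25 hepatocyte genes were higher in KO, namely Tat (1.51 ± 0.42, SE), Asl (1.14 ± 0.30) and Hpd (0.88 ± 0.20), all of amino acid metabolism (3 also when adjusted over the list alone, median 0.25, adjusted p = 0.000241, and 0.162 with an estimated correlation). Of 17 NRF2 and glutathione genes, 3 were higher (4 when adjusted over the list alone, median 0.57, adjusted p = 0.0017, and 0.61 with an estimated correlation), namely the glutathione transferases Gsta2 (3.48 ± 0.73), Gstm3 (3.46 ± 0.58) and Gstm1 (2.40 ± 0.55). The control samples of that day include 263 and 265, with Gapdh differences of 1.58 and 9.5. In KO against control on day 2 without the 3 arrays, list medians were −0.05 for NRF2, 1.14 for matrix, −1.03 for oxidation and 0.18 for hepatocyte genes. Control day 2 was then sample 264 alone. Its oxidation mean, centred per gene, was 1.716, against 0.411 in 263 and 0.518 in 265, so that median rests on the highest control sample. Cdkn1a did not pass on day 2 (0.71 ± 0.99, adjusted p = 0.705), and its sign turned without the 3 arrays (−0.35). Replication genes (median −0.09, adjusted p = 0.632) and G2/M genes (median 0.22, adjusted p = 0.433) did not pass, and the flap endonuclease Fen1 was the 1 replication gene lower (−0.69 ± 0.18). Fen1 was called lower in KO on all 3 days, including before surgery.

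KO against control on day 2 called 418 genes by limma, 201 higher and 217 lower, and 279 differed at least 2-fold; quantile normalization gave 514, with 189 higher and 325 lower. The groups of 1474 genes (20.1%) did not overlap, against 10% by chance. Without the 3 arrays the count was 36 (21 higher, 15 lower), 30 of them shared, and in a fit of only the groups compared it was 18. It was 72 without KO day 2 254, 118 without KO day 2 258, 255 without control day 2 265 and 1161 without control day 2 264. The calls of Col1a1 (adjusted p up to 0.193), Col1a2 (0.11), Lum, Col6a3, Acot1, Cpt2, Tat, Asl, Hpd, Gsta2, Gstm1 and Fen1 were each lost without KO day 2 254, and of the genes named for this day Lpl, Casp12, Anxa5, Cd36, Cyp4a14, Slc25a20, Cd163, Asns, Golm1 and Gstm3 passed without any single array. The differences of Cd163 and Asns were bounds, since both lay under 4 on every KO array; Cyp4a14 did so on 2 of 3 KO arrays (4.56 on the other) and Golm1 on 2 of 3 control arrays.

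KO against control on day 6 compared the livers late in regeneration, and cell cycle genes were lower in KO. Of 24 replication genes, 5 were lower and 19 did not pass (15 lower when adjusted over the list alone, median −1.41). This list passed with both correlations, with adjusted p = 1.49e-18 and 0.00934. The helicase subunits Mcm5 and Mcm7 were at −2.43 ± 0.36 (SE) and −1.60 ± 0.25, with Gins1 at −1.62 ± 0.39 and the clamp loader Rfc5 at −1.50 ± 0.30. Of 17 G2/M genes, 2 were lower, topoisomerase Top2a (−2.61 ± 0.41) and the mitotic kinase Pbk (−2.29 ± 0.55), and 9 were lower when adjusted over the list alone (median −1.73, adjusted p = 6.65e-11, and 0.326 with an estimated correlation). The G2/M mean, centred per gene, was −0.06, 1.94 and 4.14 in control 303, 392 and 393 and between 0.15 and 0.47 in KO, so control 303 lay under all 3 KO livers. The replication mean was between 0.86 and 1.28 in control and between −0.30 and −0.18 in KO. Cdk1 (−1.97 ± 0.66, adjusted p = 0.168) and Mki67 (−1.84 ± 0.54, adjusted p = 0.112) did not pass. The cohesin regulator Cdca5 (−2.88 ± 0.50) and the replication and repair protein Rpa2 (−1.29 ± 0.30) were also lower.

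Matrix and tumour-associated genes were higher in KO on day 6. Of 27 matrix genes, 5 were higher and 18 when adjusted over the list alone (median 1.52, adjusted p = 6.12e-17, and 0.118 with an estimated correlation), with Col6a3 at 3.38 ± 0.49 (SE), Col6a1 at 3.16 ± 0.68 and Lum at 2.84 ± 0.59. Col1a1 did not pass (2.63 ± 1.02, adjusted p = 0.263). Of 2 mesothelium markers, none passed over all genes and 1 was higher over the list alone (median 1.43), with Msln at 1.75 ± 0.65 (adjusted p = 0.225). In KO 312, 332 and 337 on day 6, the mesothelium mean, centred per gene, was 1.81, −0.89 and 3.16, and the matrix mean 0.57, −0.04 and 1.63. Of 15 oncofetal genes, 5 were higher (6 when adjusted over the list alone, median 1.30, adjusted p = 5.5e-11, and 0.026 with an estimated correlation), including Anxa5 (4.06 ± 0.36) and Golm1 (3.45 ± 0.49). None of 19 cholesterol synthesis genes passed over all genes, and 7 were higher when adjusted over the list alone (median 0.97, adjusted p = 2.52e-08, and 0.326 with an estimated correlation). Casp12 (5.71 ± 0.42), Ubd (4.96 ± 0.87), the matrix protein Mgp (4.19 ± 0.70) and the transcription factor Sox4 (4.16 ± 0.57) were higher, and the scavenger receptors Marco (−5.39 ± 1.32) and Cd163 (−4.10 ± 0.34) were lower.

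By limma, KO against control on day 6 called 127 genes, 91 higher and 36 lower, of which 116 differed at least 2-fold; quantile normalization gave 145, with 85 higher and 60 lower. Groups did not overlap for 1424 genes (19.5%), against 10% by chance. None of the 3 arrays with a high Gapdh difference belongs to the groups of this comparison. Those arrays still enter its standard errors through the spread shared by all groups, except in the fit of only the groups compared. The count was 61 without KO day 6 337, 75 without control day 6 393 and 82 without KO day 6 312, and 38 in a fit of only the groups compared. The calls of Gins1, Rfc5 (adjusted p up to 0.0738), Pbk, Rpa2, Col6a1, Lum and Marco (0.2) were each lost without KO day 6 337. Those of Mcm5, Mcm7, Top2a, Cdca5, Col6a3, Anxa5, Golm1, Casp12, Ubd, Mgp, Sox4 and Cd163 passed without any single array. For Msln, KO against control on day 6 passed without KO day 6 332 (adjusted p = 0.00354). Differences were bounds for Mcm5, Top2a, Pbk, Cdca5, Marco and Cd163, under 4 on every KO array, and for Col6a3, Col6a1, Casp12 and Msln, under 4 on every control array. Across the 3 days, 999 genes differed between genotypes on at least 1 day, 519 on day 0 only, 55 were higher on all 3 days and 8 lower on all 3.

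Day 2 against day 0 in control measured the early response of livers with the transporter. Most acute phase and neutrophil genes tested rose. A minority of glutathione, fatty acid synthesis and hepatocyte genes fell, and no list passed with an estimated correlation. Of 26 acute phase genes, 15 rose and 11 did not pass (22 rose when adjusted over the list alone, median 1.62, adjusted p = 2.65e-12, and 0.284 with an estimated correlation). The iron-scavenging protein Lcn2 rose by 7.47 ± 1.28 (SE), serum amyloids Saa2 and Saa1 by 5.59 ± 1.32 and 4.28 ± 1.02, and orosomucoid Orm2 by 5.14 ± 1.45. Of 4 neutrophil genes tested, 3 rose, which encode granule or calcium-binding proteins: Prtn3 (5.13 ± 1.08), S100a9 (4.28 ± 1.04) and S100a8 (3.99 ± 1.004), and 3 rose when adjusted over the list alone. Of 20 fatty acid oxidation genes, 4 rose, also when adjusted over the list alone, and the list did not pass (median 0.37, adjusted p = 0.289). They were Cyp4a14 (6.39 ± 1.22), the pantetheinase Vnn1 (5.98 ± 1.23), the pyruvate dehydrogenase kinase Pdk4 (3.64 ± 0.82) and Slc25a20 (0.75 ± 0.22). Of 18 fatty acid synthesis genes, 3 fell (7 when adjusted over the list alone, median −1.18, adjusted p = 2.81e-05, and 0.284 with an estimated correlation), with Thrsp at −5.65 ± 1.18 and fatty acid synthase Fasn at −2.47 ± 0.62.

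In day 2 against day 0 in control, 7 of 17 NRF2 and glutathione genes fell (8 when adjusted over the list alone, median −1.11, adjusted p = 8.46e-06, and 0.284 with an estimated correlation), with Gsta2 at −4.90 ± 0.73 (SE), Gstm3 at −3.21 ± 0.58 and Gstm1 at −3.18 ± 0.55. Of 25 hepatocyte genes, 5 fell (10 when adjusted over the list alone, median −0.42, adjusted p = 4.03e-06, and 0.0797 with an estimated correlation), including glycogen synthase Gys2 (−1.58 ± 0.37), Gnmt (−1.41 ± 0.39), Hpd (−1.34 ± 0.20) and the urea cycle gene Otc (−1.32 ± 0.32). Of 27 matrix genes, 7 rose (10 when adjusted over the list alone, median 0.97, adjusted p = 0.000104, and 0.47 with an estimated correlation), such as Col3a1 (2.52 ± 0.65) and Col4a1 (2.30 ± 0.58). Of 2 mesothelium markers, Gpm6a rose (2.85 ± 0.80, adjusted p = 0.0336; 1 when adjusted over the list alone, median 2.02), and their mean, centred per gene, lay between −0.99 and −0.43 on day 0 and between 1.13 and 1.41 on day 2. Cdkn1a rose by 3.56 ± 0.99 (adjusted p = 0.033) and asparagine synthetase Asns by 4.31 ± 0.70. Of the replication genes Mcm7 rose (1.26 ± 0.25) and Tk1 fell (−2.18 ± 0.67), and neither cell cycle list passed. Mki67 was at 0.69 ± 0.54 (adjusted p = 0.431), Cdk1 at 0.62 ± 0.66 (adjusted p = 0.576). The replication list was at a median of 0.22 (adjusted p = 0.578) and the G2/M list at 0.30 (adjusted p = 0.573). In the erythroid group of 4 genes, Klf1 (−1.58 ± 0.21) and carbonic anhydrase Car1 (−2.57 ± 0.39) fell.

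The control day 2 samples 265 and 263 had the Gapdh differences of 9.5 and 1.58. For day 2 against day 0 in control without the 3 arrays, the acute phase list had a median of 1.90 (adjusted p = 5.24e-12) with no gene called, and the glutathione list a median of −0.51 (adjusted p = 0.0207) with 1 gene called. With the beta-actin difference as a covariate, the glutathione list did not pass (median −0.59, adjusted p = 0.127). Without the 3 arrays, the other list medians were −0.45 for hepatocyte, −0.88 for fatty acid synthesis, 0.58 for fatty acid oxidation and 1.20 for matrix genes. Control day 2 was then sample 264 alone. Its oxidation mean, centred per gene, was 1.716, against 0.411 in 263 and 0.518 in 265.

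Day 2 against day 0 in control called 696 genes by limma, 383 higher and 313 lower on day 2, 469 of them at least 2-fold, and the groups of 1882 genes (25.7%) did not overlap, against 10% by chance. Without the 3 arrays 78 were called (44 higher, 34 lower), 64 of them shared, and 88 with the beta-actin difference as a covariate, both chosen after seeing the data. With the mouse as a fixed block, the fit rests on 263 and 265, the 2 mice sampled on both days. Their day 2 arrays are those with Gapdh differences of 1.58 and 9.5, and 264 has no day 0 array. In that fit 3 genes were called. These were Saa2 (6.76) and Prtn3 (4.95), which rose, and Usp2 (−4.89), named after its values were seen, which fell (adjusted p = 0.0381 for each), and the other genes named for this comparison did not pass in that fit. A fit of only the groups compared called 27. The count was 173 without control day 2 265, 179 without control day 0 265, 240 without control day 0 303, 403 without control day 0 263 and 1283 without control day 2 264. Without control day 2 265 the calls of Saa2 (adjusted p up to 0.0799), Saa1, Orm2, S100a8, S100a9, Vnn1, Pdk4, Slc25a20, Fasn, Gys2, Gnmt, Otc, Tk1, Col3a1, Col4a1 and Cdkn1a (0.112) were lost. That of Gpm6a (up to 0.114) was lost without it, without control day 2 263, without control day 0 265 and without control day 0 303. Lcn2, Cyp4a14, Prtn3, Thrsp, Gsta2, Gstm3, Gstm1, Hpd, Asns, Mcm7, Klf1 and Car1 passed without any single array. Changes were bounds for Prtn3, Asns, Mki67 and Gpm6a, under 4 on every day 0 array, and for Klf1 and Car1, under 4 on every day 2 array, while Cdk1 was under 4 on all of both days. This does not hold for the values from the fixed block.

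Day 6 against day 0 in control measured the later response, with mouse 303 the 1 mouse sampled on both days. Proliferation, interferon and acute phase genes rose. The list means of 303, 392 and 393, centred per gene, were −0.06, 1.94 and 4.14 for G2/M, 1.28, 0.86 and 1.07 for replication, 1.26, 3.35 and 0.68 for interferon, and 1.17, 0.80 and −0.75 for acute phase genes. Of 17 G2/M genes, 10 rose and 7 did not pass (17 rose when adjusted over the list alone, median 3.02, adjusted p = 1.05e-20, and 0.123 with an estimated correlation). Cdc20 rose by 4.86 ± 0.87 (SE), the ubiquitin-conjugating enzyme Ube2c by 4.63 ± 1.11, Cdk1 by 4.62 ± 0.66, survivin Birc5 by 4.27 ± 0.86 and Mki67 by 3.97 ± 0.54. Of 24 replication genes, 11 rose (19 when adjusted over the list alone, median 1.21), and the list passed with both correlations (adjusted p = 7.51e-17 and 0.0164). Mcm6 rose by 3.93 ± 0.58, Mcm5 by 3.05 ± 0.36, the licensing factor Cdt1 by 2.61 ± 0.69 and the primase Prim1 by 2.57 ± 0.44. Of 22 interferon response genes, 9 rose (19 when adjusted over the list alone, median 2.64, adjusted p = 1.17e-17, and 0.123 with an estimated correlation), such as Usp18 (5.28 ± 0.86), Ifit1 (4.89 ± 1.22), Oas1a (4.39 ± 0.78) and the regulator Irf7 (3.79 ± 0.80). None of 4 lymphocyte markers passed, over all genes or over the list alone (median −0.02), and their mean in these mice was −0.36, 1.05 and −0.98. Of 26 acute phase genes, 5 rose (13 when adjusted over the list alone, median 1.37, adjusted p = 3.29e-12, and 0.227 with an estimated correlation), with Lcn2 at 6.67 ± 1.28.

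Other groups also changed on day 6 in control. Of 22 macrophage genes, 2 rose, Marco (5.78 ± 1.32, SE) and the pore-forming Mpeg1 (2.65 ± 0.45; 2 when adjusted over the list alone, list median 1.01, adjusted p = 5.92e-05, and 0.3 with an estimated correlation). The macrophage mean, centred per gene, was 1.655, 0.633 and −0.784 in 303, 392 and 393 on day 6. On day 0 it lay between −0.946 and −0.328 in control, so 393 showed no rise. Of 21 p53 targets, 2 rose, Ddit4 (2.82 ± 0.46) and Aen (1.29 ± 0.32), and 6 when adjusted over the list alone (median 0.51, adjusted p = 0.00107, and 0.123 with an estimated correlation). Cdkn1a did not pass (3.50 ± 0.99, adjusted p = 0.0661), and the histone variant H2ax was the 1 double-strand break gene that rose (1.49 ± 0.38; 4 when adjusted over the list alone, list median 0.20, adjusted p = 0.0112, and 0.3 with an estimated correlation). Prtn3 rose by 5.50 ± 1.08 and Klf1 fell by 1.76 ± 0.21. Cyclin D1 did not pass (Ccnd1, 1.40 ± 0.57, adjusted p = 0.213).

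Day 6 against day 0 in control called 209 genes by limma, 155 higher and 54 lower, 183 of them at least 2-fold, with non-overlapping groups for 1712 genes (23.4%, against 10% by chance). With the mouse as a fixed block, which rests on mouse 303 alone, 2 genes were called. They were Prtn3 (7.13) and BC023105 (7.75, named after its values were seen), each with adjusted p = 0.048. The other genes named for this comparison did not pass in that fit. Its residual spread comes only from how the day 2 changes of mice 263 and 265 differ. Neither the calls made nor those lost therefore measure how the day 6 response varies between mice. The count was 54 without control day 0 265, 55 without control day 6 392, 93 without control day 0 303 and 109 without control day 0 263, and 19 in a fit of only the groups compared. No array of this comparison exceeded a Gapdh difference of 1, and the highest was 0.94 in control day 6 303. Arrays above 1 still enter its standard errors through the spread shared by all groups, except in the fit of only the groups compared. The calls of Birc5 (adjusted p up to 0.0554), Ube2c, Cdt1, Ifit1, Irf7, Lcn2, Marco, Aen, H2ax and Prtn3 (0.0531) were each lost without control day 6 392. Cdc20, Cdk1, Mki67, Mcm6, Mcm5, Prim1, Usp18, Oas1a, Mpeg1, Ddit4 and Klf1 passed without any single array. Changes were bounds for Ube2c, Cdk1, Birc5, Mki67, Mcm6, Mcm5, Usp18, Ifit1, Oas1a, Irf7, Marco and Prtn3, under 4 on every day 0 array, and for Klf1, under 4 on every day 6 array. This does not hold for the values from the fixed block.

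Day 2 against day 0 in KO was the early response of the knockout livers. No single gene passed, while acute phase genes as a list were higher on day 2 and glutathione genes lower. All 26 acute phase genes had positive values; none passed over all genes and 16 rose when adjusted over the list alone (median 1.21, adjusted p = 1.58e-26, and 0.121 with an estimated correlation). The pentraxin Apcs had 2.37 ± 0.47 (SE, adjusted p = 0.195) and Saa1 had 2.25 ± 0.88 (adjusted p = 0.679). Of 17 glutathione genes, 6 fell when adjusted over the list alone and none over all genes (median −0.91, adjusted p = 6.08e-11, and 0.121 with an estimated correlation), with Gstp1 at −0.81 ± 0.18 (adjusted p = 0.353). KO day 0 258 stood with the day 2 arrays in both lists, which made both shifts smaller. Its acute phase mean, centred per gene, was 1.02, with −1.46 to −0.30 in the other day 0 arrays and 0.38 to 1.39 on day 2. Its glutathione mean was −0.21, with 0.36 to 0.75 and −0.48 to −0.30. Its neutrophil mean was 0.754, with −2.269 to −0.826 in the other KO day 0 arrays and −0.476 to 1.44 on day 2. In KO on day 6 the neutrophil mean lay between 0.394 and 1.55. The neutrophil list had too few tested genes for camera. The endothelial list was lower, with none of 17 genes passing over all genes and 4 when adjusted over the list alone (median −0.65, adjusted p = 2.22e-08, and 0.213 with an estimated correlation). G2/M genes had a median of −0.73 (adjusted p = 0.00113, and 0.624 with an estimated correlation) and no gene passed, with Mki67 at −1.28 ± 0.47 (adjusted p = 0.634).

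By limma 0 genes passed in day 2 against day 0 in KO, with 439 at an unadjusted p under 0.05 and a smallest adjusted p of 0.171; with the mouse as a random or fixed block the count was also 0. Array weights gave 140 genes. Without KO day 0 258 the count was 32, and it was 1 each without KO day 0 254 and without KO day 0 337; without the 3 arrays it was 0. Groups of 188 genes (2.57%) did not overlap, against 2.38% by chance.

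In day 6 against day 0 in KO, interferon response genes rose. All 22 interferon response genes had positive values; 4 rose over all genes and 22 when adjusted over the list alone (median 2.52). The list passed with both correlations, with adjusted p = 3.01e-48 and 0.0134. The antiviral synthetases Oasl2 and Oas1a rose by 4.88 ± 0.88 (SE) and 4.57 ± 0.68, Ifit2 by 4.29 ± 0.74 and Irf7 by 3.93 ± 0.69. Outside the list, the interferon-inducible Ifi209 (4.22 ± 0.55), Ifi27l2a (3.42 ± 0.58) and Rtp4 (3.36 ± 0.52) rose, as did the Fc receptor Fcgr1 (3.16 ± 0.54). The remaining called genes were Ifi204 (1.69) and Fgl2 (1.36), named after their values were seen. Of 4 lymphocyte markers, none passed over all genes and 2 rose over the list alone (median 1.02), with the granzyme Gzmb at 2.15 ± 0.56 (adjusted p = 0.205). None of 22 macrophage genes passed, over all genes or over the list alone, and the list was higher (median 0.46, adjusted p = 0.000923, and 0.66 with an estimated correlation). In KO 312, 332 and 337 on day 6, the lymphocyte mean was 1.14, 1.12 and 0.19, and the interferon mean 1.69, 4.53 and 0.90. All 26 acute phase genes had positive values, and none passed over all genes or over the list alone (median 0.86, adjusted p = 6.55e-15, and 0.413 with an estimated correlation). Proliferation genes did not pass, with Mki67 at a mean of 5.03 in KO on both days (adjusted p = 1) and Cdk1 at 0.35 ± 0.57 (adjusted p = 1); the G2/M list had a median of 0.04 (adjusted p = 0.458) and the replication list −0.19 (adjusted p = 0.0632).

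In total, day 6 against day 0 in KO called 10 genes by limma, all higher and all at least 2-fold, with 398 genes at an unadjusted p under 0.05. Groups of 256 genes (3.5%) did not overlap, against 2.38% by chance. With the mouse as a fixed block the 1 gene called was the heat shock gene Hspa1a (−3.66, adjusted p = 0.00748), named after its values were seen, and the 10 genes above did not pass in that fit. The heat shock list mean of the mice in these pairs, 312, 332 and 337, was 1.05, 1.42 and 1.30 on day 0, against −0.47 to −0.04 in the other 3 KO day 0 arrays. The count was 2 without KO day 6 332, 3 without KO day 6 312, 16 without KO day 0 258 and 45 without KO day 6 337. Without the 3 arrays, of which KO day 0 337 enters here, it was 6 (5 shared) and the interferon list had a median of 2.58 (adjusted p = 7.69e-39). Array weights gave 37. Ifi209 passed without any single array, and the calls of Oasl2 (adjusted p up to 0.27), Oas1a (0.0708), Ifit2 (0.165), Irf7 (0.203), Ifi27l2a, Rtp4, Fcgr1, Ifi204 and Fgl2 were each lost without KO day 6 332. For Gzmb, day 6 against day 0 in KO passed without KO day 6 337 (adjusted p = 0.000569). Changes were bounds for Ifi209, Fcgr1, Ifi204 and Gzmb, under 4 on every KO day 0 array.

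The day 2 response, KO minus control, tested whether the genotypes responded differently on day 2. No gene passed, while hepatocyte genes as a list had a more positive response in KO. Of 25 hepatocyte genes, none passed over all genes and 4 when adjusted over the list alone (median 0.45), and the list passed with both correlations (adjusted p = 9.6e-08 and 0.0265). Its member Hpd had 1.53 ± 0.27 (SE, adjusted p = 0.0733), and 1.51 with adjusted p = 0.0461 with the mouse as a random block. In that blocked fit 8 genes were called, 2 higher and 6 lower. The other higher one was the erythroid factor Klf1 (1.61). Its KO values lay between 2.77 and 3.36 on both days, too near background to show a fall, so this value holds the fall in control and no measured difference in response. The 6 lower, named after their values were seen, were Slpi (−3.88), Il17rb (−3.31), Faap20 (−2.01), Reep5 (−1.91), Prune1 (−1.63) and Cystm1 (−1.36). The P450 list had a median of 0.52 with 1 gene higher when adjusted over the list alone (adjusted p = 0.00014, and 0.409 with an estimated correlation). The matrix list had a median of −0.95 (adjusted p = 0.007, and 0.655 with an estimated correlation), and the oncofetal list −1.27, with 0 and 5 genes lower when adjusted over the list alone (adjusted p = 0.0149, and 0.587 with an estimated correlation). The acute phase list had a median of −0.60 (adjusted p = 0.0421, and 0.756 with an estimated correlation). G2/M genes had a median of −0.997 (adjusted p = 0.0421, 0.756 with an estimated correlation and 0.0684 with the random block). Asns (−4.28 ± 0.92, adjusted p = 0.0839) and Cdkn1a (−3.09 ± 1.32, adjusted p = 0.301) did not pass. Asns lay under 4 on every KO array of both days and on every control day 0 array, and Il17rb on every control day 0 array.

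For the day 2 response, KO minus control, limma called 0 genes, with 1070 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0733. The control day 2 samples with high Gapdh differences are part of this contrast. Leaving out the 3 arrays gave 2 genes, and the hepatocyte list had a median of 0.27 (adjusted p = 3.93e-08), the acute phase list −0.54 (adjusted p = 0.0232) and the G2/M list −1.04 (adjusted p = 0.0622). With the beta-actin covariate the P450 list (median 0.23, adjusted p = 0.106) and the acute phase list (−0.32, adjusted p = 0.0697) did not pass. The count was 228 without control day 2 264, 74 without control day 2 263, 3 without KO day 2 254, 2 without control day 0 263 and 1 each without KO day 0 254 and KO day 0 258.

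The day 6 response, KO minus control, was more negative for cell cycle genes. Of 24 replication genes, 4 were lower and 19 when adjusted over the list alone (median −1.55), and the list passed with both correlations (adjusted p = 6.7e-27 and 0.00148). Mcm6 had −4.42 ± 0.76 (SE), Mcm5 −3.25 ± 0.47, Prim1 −3.18 ± 0.58 and Mcm7 −2.31 ± 0.33. Mean Mcm6 went from 3.13 to 7.06 in control between days 0 and 6, and from 5.61 to 5.11 in KO. Of 17 G2/M genes, 2 were lower and all 17 when adjusted over the list alone (median −3.27, adjusted p = 1.56e-25, and 0.0698 with an estimated correlation), with Mki67 at −3.97 ± 0.72 and Top2a at −3.40 ± 0.54. Cdk1 did not pass (−4.26 ± 0.87, adjusted p = 0.0658), but did with the mouse as a random block (−4.23, adjusted p = 0.0486). Of 17 double-strand break genes, Rpa2 was lower (−2.11 ± 0.39), and 3 when adjusted over the list alone (median −0.47, adjusted p = 8.39e-07, and 0.0698 with an estimated correlation). The microtubule regulator Stmn1 (−3.75 ± 0.63) and Cdca5 (−3.52 ± 0.66) were lower, as were the condensin subunit Smc2 (−3.20 ± 0.44) and the histone chaperone Dnajc9 (−1.70 ± 0.26), both named after their values were seen. Klf1 was the 1 gene with a positive value (1.64 ± 0.28). Its KO values lay between 2.62 and 3.36 on days 0 and 6, too near background to show a fall, while control went from 4.58 to 5.36 on day 0 to 3.04 to 3.34 on day 6, so no difference in response was measured. Of the genes with negative values, Mcm6, Mcm5, Mki67, Top2a, Cdk1, Cdca5, Smc2 and Usp18 lay under 4 on every control day 0 array, and Mcm5, Top2a and Cdca5 also on every KO array of both days. The interferon list did not pass (median −0.06, mean 0.08, adjusted p = 0.726), and Usp18 had −1.72 ± 1.14 (adjusted p = 1).

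**Figure D4:**
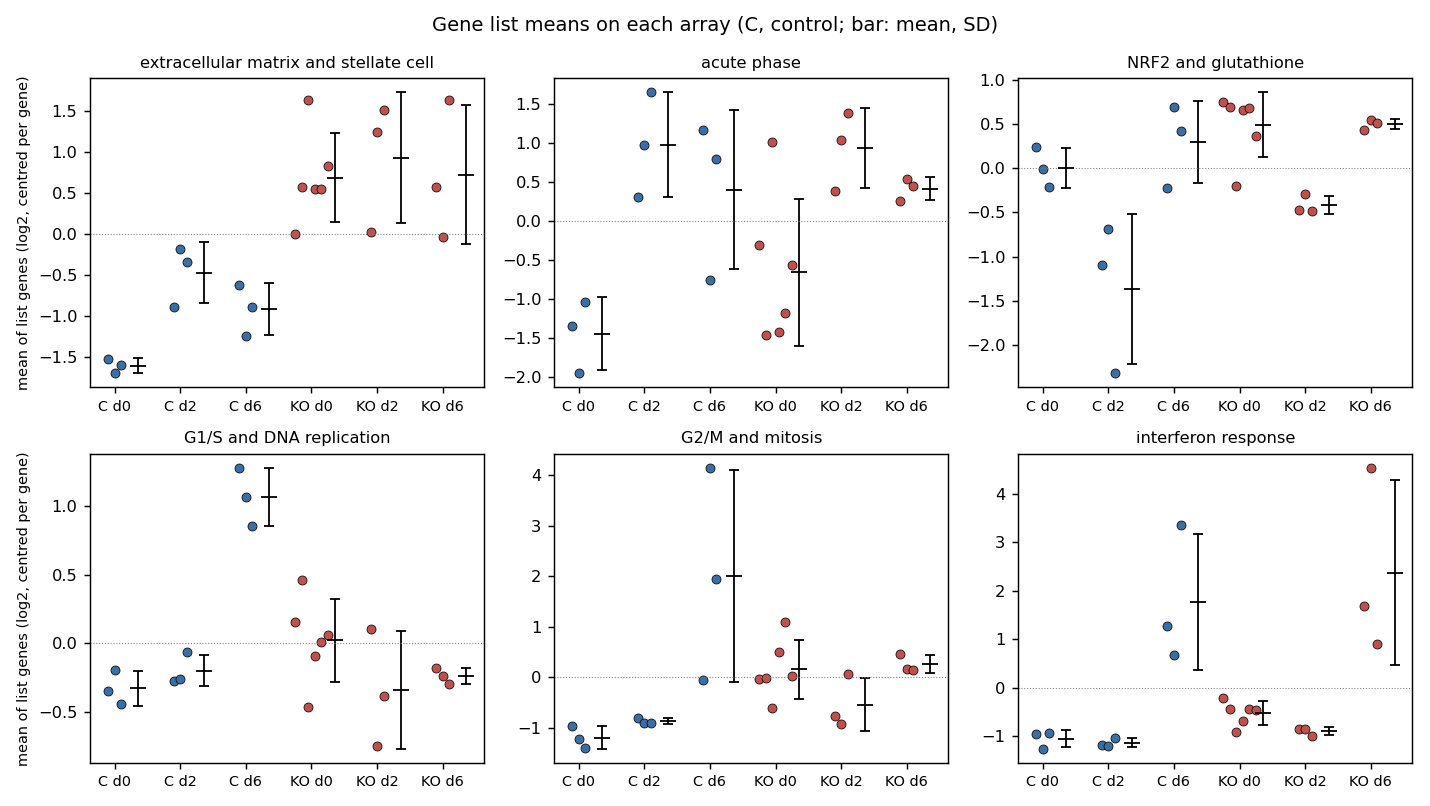
Mean of 6 gene lists on each array, centred per gene (log2), by genotype and day; points are samples and bars give mean and SD. Replication genes averaged 1.07 in control day 6 and −0.24 in KO day 6, and interferon genes 1.76 and 2.37.

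The day 6 response, KO minus control, called 12 genes by limma, 1 higher and 11 lower, with 392 at an unadjusted p under 0.05. The fit without the 3 arrays called 13, 10 of them shared. The count was 4 without control day 0 303, 5 without KO day 6 312, 7 each without KO day 6 332, KO day 6 337 or control day 0 263, and 41 without control day 6 303; array weights gave 50. Mcm5, Mcm7, Smc2 and Dnajc9 passed without any single array, whereas Mcm6 (adjusted p up to 0.0737), Prim1 (0.0852), Mki67 (0.0845), Top2a (0.0526), Stmn1 (0.0688), Cdca5 (0.104), Rpa2 (0.103) and Klf1 (0.0582) lost the call without control day 0 303.

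The responses of the genotypes were set side by side across genes, which are not independent replicates. Pearson's r between the log2 changes in control and in KO was 0.349 on day 2 and 0.553 on day 6 over 7320 genes, with Spearman's rho at 0.193 and 0.436. The genotypes share no array. Of the 696 genes called in control on day 2, 506 (72.7%) had the same sign in KO, and of the 209 called on day 6, 163 (78%) did. On day 6, 4 genes rose in both genotypes, against 0.212 expected from independent lists. The day 2 coefficient ranged from 0.212 without KO day 2 258 to 0.445 without KO day 2 250.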

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

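Tests of the interferon pattern and of KO day 0 258, and the count of interaction splits that set each mouse in 1 genotype, were chosen after the results were seen. Both tests of the control day 2 response were chosen after its high 3' to 5' differences were seen, and the other splits of the samples were set beforehand.

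In KO on day 0, the group of 6, 3 of 41 values tested with Dixon's ratio had a sample far from the rest, where chance gives about 1 in 20. The gap divided by the range was 0.654 for Col1a1 and 0.797 for Cyp7a1, both in KO day 0 258, and 0.857 for the Gapdh 3' to 5' difference in KO day 0 337. That difference lay above every control day 0 sample in KO day 2 250 (0.23), control day 6 303 (0.94), control day 2 263 (1.58), KO day 0 337 (2.03) and control day 2 265 (9.5). These control probe sets were not tested as genes; the Gapdh difference chose the 3 arrays left out in an alternative, and the beta-actin difference was the covariate of another.

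By the interaction term, 12 genes passed the test for a day 6 response that differs between genotypes. The KO minus control difference in log2 was −4.42 for Mcm6, −3.97 for Mki67, −3.75 for Stmn1, −3.52 for Cdca5, −3.40 for Top2a, −3.25 for Mcm5, −3.20 for Smc2, −3.18 for Prim1, −2.31 for Mcm7, −2.11 for Rpa2, −1.70 for Dnajc9 and 1.64 for Klf1. KO values of Klf1 were near background on both days (2.62 to 3.36), where no fall can be seen, so its value shows no difference in response. Those of Mcm5, Top2a and Cdca5 were under 4 in KO on both days, which bounds any fall there. Among lists past the test with an estimated correlation, the median was −1.55 for replication genes on day 6 and 0.445 for hepatocyte genes on day 2.

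The first pattern is the day 2 response in control, in which 2 of 3 day 2 arrays had a high 3' to 5' difference. RNA degradation as the whole source of the acute phase rise is argued against by the beta-actin covariate, with which the list median was 1.44 against 1.62. For other genes it stays open: of 709 called from the high-difference arrays against their own day 0 arrays, 532 (75%) went the same way in sample 264 against control day 0 303. Their median signed difference there was 0.39, against 1.34 in the high-difference arrays, and 1 array cannot exclude it. A response to surgery, the biological explanation of the design, also stays open.

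The second pattern is the interferon rise on day 6 in both genotypes. In KO, a difference in the interferon list between the sets of mice before surgery is argued against. KO mice later sampled on day 6 differed by −0.00758 on day 0 from those sampled on day 2, against a mean rise of 2.90. In control this day 0 difference was 0.17, against a mean rise of 2.81, but it rests on control 303 alone. The other control day 6 mice have no day 0 array, so a difference before surgery stays open for them. RNA quality as the whole source is argued against too, with a smaller median shift of 2.64 under the beta-actin covariate. An exposure shared by the mice kept to day 6 stays open: rises over the same mouse's day 0 sample were 1.36, 2.38 and 4.96 in KO and 2.20 in control 303, and no unoperated day 6 mice were analysed here. Surgery itself cannot be told apart from such an exposure by the value of 1.36 or any other here.

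The third pattern is KO day 0 258, whose acute phase list mean of 1.02 lay within the KO day 2 samples. By acute phase genes alone, a swap with a KO day 2 array is argued against. The lowest of those lay 0.688 above the highest other KO day 0 array. For day 2 against day 0 in KO, the split exchanging KO day 0 258 with KO day 2 250 gave 164 genes, against 0 for the real groups. The glutathione mean of KO day 2 250 was −0.468, under the other KO day 0 arrays. Its matrix mean of 0.021 lay within their range, so the lists disagree and a swap with that array stays open. For KO day 0 258, RNA quality is argued against by its Gapdh difference of 0.12. A wrong time label and an inflamed liver before surgery cannot be told apart by its mean of 1.02.

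Other splits of the same arrays were refitted in the model of all groups. For KO against control on day 0, 1 of 84 splits, the real one, gave 707 genes and the highest other gave 5. The other splits mix the genotypes within a group, which adds their difference to the spread, so low counts there are partly fixed in advance. Chance is therefore not excluded by this count. For day 6 against day 0 in KO, 1 of 84 splits, the real one, gave 10 genes (highest other 5). Among 8 splits that also part 3 pairs the highest other gave 4. For the day 6 response, KO minus control, 2 of 100 splits drawn gave at least 12 genes. The highest other, 30, kept the real day 6 groups and exchanged day 0 arrays, so the count alone does not establish a different response. All but 5 of these splits set samples of a mouse in different genotypes; among those 5 the highest other gave 1, and 5 are too few for a share under 0.05. For day 2 against day 0 in KO and the day 2 response, KO minus control, the real count was 0, so that all 84 and all 100 splits gave as many whatever the data, and nothing on chance follows. The highest others gave 164, with KO day 2 254 and 258 grouped with KO day 0 258, and 55, with the real day 2 groups and day 0 arrays exchanged, which points to a structure of the samples. Among 8 splits parting 3 pairs, and among 3 that set each mouse in 1 genotype, the highest other was 0. Comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. In each of them 1 split, the real one, was as large. The real and highest other counts were 418 and 12 for KO against control on day 2 and 127 and 21 on day 6. They were 696 and 3 for day 2 against day 0 in control (0 among 4 splits parting 2 pairs) and 209 and 3 for day 6 (2 among 6 parting 1 pair).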

How the results depend on the processing

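Leaving out the 3 arrays with a high Gapdh difference, the beta-actin covariate and the same-mice day 0 arrays were chosen after seeing the data; the other settings were planned. No scaling moved the median of all genes by more than 0.1, and of 114 list results that passed none turned direction under quantile normalization or median centring. Over settings other than leave-one-out, counts stayed within 1.5 times of the reported value in 76 cases and moved in 36. Named gene results stayed on their side of the threshold in 1850 cases, lost the call in 326, gained it in 39 and turned sign in 10. Signal near background limits the low genes: the filter leaves 649 of 7320 tested genes at or under log2 4 on every array of at least 1 group. The cause of the changes below was not tested.

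Counts moved as follows. Without a filter, day 6 against day 0 in KO had 6 genes and the day 2 response, KO minus control, had 4; with the filter at 6 the day 6 response, KO minus control, had 5. The day 2 response, KO minus control, also had 10 with the mean of probe sets, 1 with quantile normalization, 2 with median centring, 1 with trend and robust, 10 in a fit of only the groups compared and 8 with the mouse as a random block. With every probe set tested, which tests more features, KO against control on day 2 had 730, day 2 against day 0 in control 1208, the day 2 response, KO minus control, 3 and the day 6 response, KO minus control, 19. Array weights gave 1414, 111 and 275 for KO against control on days 0, 2 and 6, and 214 and 571 for days 2 and 6 against day 0 in control. They gave 140 and 37 for days 2 and 6 against day 0 in KO and 50 for the day 6 response, KO minus control. In a fit of only the groups compared, with fewer arrays to estimate the spread, KO against control had 18 on day 2 and 38 on day 6. Control had 27 on day 2 and 19 on day 6 against day 0. That fit also drops the spread pooled over all groups. The median SD was 0.475 in control day 2 and 0.214 to 0.3 in the other groups. Standard errors of the main model may therefore be too small for control day 2.

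With the mouse as a fixed block, day 2 against day 0 in control had 3, day 6 against day 0 in control 2 and day 6 against day 0 in KO 1. The random block ended the list calls of NRF2 genes in KO against control on day 0 (0.0637) and, in the day 2 response, KO minus control, of G1/S (0.0576), G2/M and fatty acid oxidation genes (both 0.0684). In the day 6 response, KO minus control, it ended that of lipid droplet genes (0.0695) and added that of heat shock genes (0.0271). Among named genes it changed the calls of Cyp7b1, Cdk1 and the 8 of the day 2 response, KO minus control, given above. The fixed block, with few pairs, ended 59 calls of named genes and added those of BC023105 and Hspa1a given above. Lists were tested with the random block alone. The pairing changed no other call of a named gene or list and moved no other count by over 1.5 times, though many genes not named here changed. The random block gave 925 for day 2 against day 0 in control (696 shared), 241 for day 6 (209 shared), 720 for KO against control on day 0 (698 shared) and 393 on day 2 (393 shared). Without the 3 arrays KO against control on day 2 had 36, day 2 against day 0 in control 78, day 6 against day 0 in KO 6 and the day 2 response, KO minus control, 2. With the beta-actin covariate KO against control on day 2 had 71, day 2 against day 0 in control 88 and the day 2 response, KO minus control, 1. The covariate also ended the list calls of NRF2 genes in KO against control on day 0 (0.0746) and day 2 (0.951) and in day 2 against day 0 in control (0.127), and there of P450 genes (0.266). In KO against control it ended those of immediate early genes on day 2 (0.327) and of double-strand break (0.0767) and lipid droplet genes (0.226) on day 6. In the day 2 response, KO minus control, it ended those of G1/S (0.131), P450 (0.106), acute phase (0.0697) and cholangiocyte genes (0.0572), and in the day 6 response, KO minus control, that of P450 genes (0.0722). With only the day 0 arrays of the same mice, day 6 against day 0 in KO had 6 (1 shared). The agreement of the day 6 response was 0.606 with the filter at 6, the spread among KO day 0 livers 0.195 without a filter, and 8 of 114 list results passed with an estimated correlation.

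Signs turned for Mki67 in day 6 against day 0 in KO (−0.0544 with quantile normalization, −0.045 with the random block, −0.417 with the fixed block and with the same-mice arrays). Those of Cdk1 in day 6 against day 0 in KO (−0.0367 with the fixed block and with the same-mice arrays) turned too. So did Plin2 (−0.0142) and Alb (−0.0458) in KO against control on day 0 with median centring, and Cdkn1a in KO against control on day 2 (−0.347 without the 3 arrays, −0.399 with the covariate). None of these passed the test in any of the settings named.

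Leaving out each array in turn, KO against control gave 357 to 690 genes on day 0, 72 to 1161 on day 2 and 61 to 161 on day 6. Control gave 173 to 1283 on day 2 and 54 to 298 on day 6 against day 0, and KO 0 to 32 on day 2 and 2 to 45 on day 6. The day 2 response, KO minus control, gave 0 to 228 and the day 6 response, KO minus control, 4 to 41. The agreement ran from 0.212 to 0.445 on day 2 and from 0.467 to 0.583 on day 6, and the spread among KO day 0 livers from 0.271 to 0.307. Plin2 in KO against control on day 0 ran from −0.417 to 0.338, Alb from −0.0167 to 0.0533, and Mki67 in day 6 against day 0 in KO from −0.167 to 0.185. Of the named genes past the threshold, 33 of 48 passed in every omission for KO against control on day 0, 11 of 23 on day 2 and 13 of 20 on day 6. For control this was 12 of 32 on day 2 and 11 of 21 on day 6, and for KO on day 6 it was 1 of 10.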

Other observations

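On day 0, a few inflammatory and sterol genes were also higher in KO. The tests of the region around Abcb4 below were chosen after the results were seen. In KO against control on day 0, of 19 NF-kB targets and chemokines 3 were higher, also when adjusted over the list alone: the adhesion molecules Icam1 (2.39 ± 0.64, SE) and Vcam1 (2.30 ± 0.53) and the chemokine Cxcl16 (1.77 ± 0.43). The list median was 0.76 (adjusted p = 0.00285, and 0.437 with an estimated correlation). Of 14 immediate early genes 4 were higher and 5 over the list alone, including Klf6 (3.06 ± 0.41) and Jun (1.47 ± 0.44, median 0.97, adjusted p = 0.0108, and 0.295 with an estimated correlation). Of 19 cholesterol synthesis genes 3 were higher, also over the list alone, including squalene epoxidase Sqle (2.76 ± 0.52) and Hmgcs1 (1.70 ± 0.41, median 0.57, adjusted p = 0.0327, and 0.593 with an estimated correlation). Of 4 erythroid genes, Klf1 (−1.89 ± 0.18) and Car1 (−2.46 ± 0.33) were lower. Klf1 lay under 4 on every KO day 0 array and Cxcl16 on every control day 0 array, so their differences are bounds. Klf6, Sqle, Klf1 and Car1 passed without any single array. The calls of Icam1, Cxcl16, Hmgcs1 and Jun were lost without control day 0 265, and that of Vcam1 without control day 0 303; Icam1, Hmgcs1 and Jun also lost it without other arrays.

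In control livers, few circadian clock genes passed after surgery. For day 2 against day 0 in control, 2 of 15 fell, Per3 (−3.64 ± 1.03, SE) and Cry2 (−1.39 ± 0.41), and over the list alone 1 rose and 7 fell (median −1.24, adjusted p = 0.0362, and 0.284 with an estimated correlation). Both gene calls were lost without control day 2 265 and without other arrays, and its Gapdh difference was 9.5; Per3 lay under 4 on every day 2 array. For day 6 against day 0 in control, none passed over all genes and 6 fell over the list alone (median −1.38, adjusted p = 0.00121, and 0.123 with an estimated correlation). The day 6 response, KO minus control, had a list median of 1.09 (adjusted p = 0.00292, and 0.111 with an estimated correlation). On day 0 the list mean, centred per gene, lay between 0.717 and 0.768 in control and between −0.423 and 0.572 in KO. On day 6 it lay between −0.673 and 0.279 in control and between −0.485 and 0.0185 in KO. The KO day 0 arrays were divided: 250, 254 and 337 lay between 0.468 and 0.572, and 258, 312 and 332 between −0.423 and −0.173. All lay under the control range on day 0, some of them close to it, and the genotypes overlapped on day 6. The time of day of sampling is not given in the sources used here.

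The control day 6 mice differed in cell cycle genes. The mean of the G2/M list, centred per gene, was −0.06 in 303, 1.94 in 392 and 4.14 in 393, while that of the replication list was 1.28, 0.858 and 1.07. Interferon list means were 1.26, 3.35 and 0.676 in the same mice. On day 6 the KO samples lay between 0.146 and 0.472 for G2/M and between −0.3 and −0.181 for replication genes.

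A hypothesis of strain origin was tested, since the strain labels of KO and control differ. A segment around Abcb4 derived from the strain of the stem cells could carry differences unrelated to the knockout. Within 10 Mb of Abcb4, 4 of 18 tested genes (22.2%) differed in KO against control on day 0, against 701 of 7295 elsewhere (9.61%; Fisher's exact p = 0.0881, two-sided), which leaves it open for that day. On day 2, 3 of 18 (16.7%) differed there against 414 elsewhere (5.68%; Fisher's exact p = 0.0795), and on day 6, 3 of 18 against 122 elsewhere (1.67%; p = 0.0033). Adjusted over the 4 tests these were 0.0881, 0.0881 and 0.0132 for days 0, 2 and 6. Of genes different in the same direction on all 3 days, 2 of 18 (11.1%) lay there, Abcb1b and Cd36, against 60 elsewhere (0.822%; Fisher's exact p = 0.00992, and 0.0198 adjusted). An excess on day 6 and on all 3 days is what a strain segment would predict. Both results share Abcb1b and Cd36, so they are not separate. The third gene of day 6, Gnai1, had 0.773, −0.307 and 1.59 on days 0, 2 and 6. It passed by limma on day 6 only (adjusted p = 0.0285), which a fixed segment does not predict. A strain segment therefore stays open, and an effect of the knockout on neighbouring transporters was not tested.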
